A study of Oryza sativa with 32 samples.

How the data were processed

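Total RNA from root and shoot of rice (Oryza sativa cv. Nipponbare) was biotin-labelled and hybridized to a 1-colour Affymetrix rice array, per the labels. The plants were wild type or belonged to 1 of 3 transgenic lines. These were AGR1/7, then AGR1/8, and finally AGR3/8, and the labels call them independent. All carry OsANT1:HvAlaAT, a barley alanine aminotransferase coding sequence behind the promoter of the rice OsANT1 gene. The plants grew in hydroponics at 28 °C, 70% relative humidity, a 14 h day, a 10 h night and a light intensity of 750 µE, with 5 mM ammonium as nitrogen source. The RNA came from maximum tillering and was taken at mid-day. The 32 arrays fell into 8 groups of 4 replicates, which the labels call biological replicates.

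The deposited table gives 1 intensity per probe set and array. Each value is an intensity that the authors placed on a linear scale, with 1 decimal and a highest value of 23283.7. There were 113 exact zeros. The mean after trimming 2% of the probe sets at each end was 99.99 on every array, so the deposited intensity had been scaled per array to a common target. The software that made the intensity values is not given in the sources used here. For arrays, their number limits the precision. A uniform scaling cannot register a change in total RNA per cell, and probe sets near background give changes that the added constant compresses.

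Intensities were transformed as log2(intensity + 16). The medians of the arrays within a tissue differed too little to meet the limit set for further scaling, so none was applied. Of 57381 probe sets, 187 control probe sets were left out, 64 of them for reporter sequences. In each tissue the dimmest 33.3% by mean log2 intensity was left out, and 38129 probe sets were tested. The fit across tissues used all 32 arrays and also tested 38129 probe sets. 34190 probe sets were tested in both tissues. The annotation table for this array matched 22436 probe sets to a single rice gene, 95 to several genes and 34663 to none. 3193 probe sets, for 2458 genes, had a descriptive gene name. The remaining genes are given by their LOC identifier, and unmatched probe sets are described as such. The rice gene table of assembly ASM3414082v1 was used for names and for the order of neighbouring genes. Coordinates were not used here.

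Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior (lmFit and eBayes). Each tissue had its own fit over 16 arrays with 4 groups. The contrasts were the mean of the 3 line means minus the wild type mean, called the transgenic mean below, each line minus wild type, and the moderated F test of differences among the lines. The fit over all 32 arrays gave root minus shoot in wild type and the difference between the transgenic effects in root and in shoot. P values were adjusted by Benjamini-Hochberg over the probe sets tested and called under 0.05. Changes are log2 differences with the standard error (SE) of the fit, group levels are mean intensities with SD over 4 arrays. A change of a probe set is described by how many of the 12 transgenic arrays lay above the wild type mean.

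Gene lists were tested with limma's camera at a preset correlation of 0.01, with the correlation estimated beside it and with fry, which tests whether a list's members move on balance in a single direction without comparing them to other genes. The planned lists were defined by words in gene names before the data were examined, as were the groups, contrasts, thresholds and the other settings listed below unless said otherwise. The annotation carries short symbols for most genes, so 14 planned lists in each tissue had the 5 or more tested probe sets required and the rest were not tested. A further 18 lists defined by gene symbols were added after the data had been seen, with their own adjustment, and are called lists by symbol here. No gene name in the table matched alanine aminotransferase or the promoter's gene, so the planned look at those genes was not run.

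The genes named were chosen by a rule fixed beforehand. It took the 10 higher and 10 lower probe sets with the largest transgenic mean change among those called with the same sign in the 3 lines, the 5 highest and 5 lowest per line, the 10 with the largest mean change among those called in all 3 lines, and up to 4 called members of each list. Where a transport or assimilation list had none called, its brightest members were taken. The same rule was applied to the added lists. The text names a part of them.

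The pipeline was tested on simulated data with the spread of each probe set on these arrays. Among 50 changed probe sets of each size, the transgenic mean contrast in root recovered 36% at 0.5 log2, 88% at 1 and 100% at 2. In shoot the figures were 42%, 94% and 98%. The difference between tissues recovered 20%, 58% and 98%. These figures describe the simulated data only. On the real arrays the lines differed from each other on many probe sets, and leaving out single arrays moved the counts of calls. Recovery on the real arrays may therefore be lower than in the simulation.

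The other settings tried were quantile normalization, median centring, no dim filter or a stricter one, added constants of 1 and 64, no intensity trend, array weights, the replicate number as a block, each array left out in turn, all 32 arrays in a single fit, the line as a random unit (statmod 1.5.0), and a minimum change of 1 log2. The joint removal of 2 arrays that stood apart was added after the data had been seen, and so was the line and replicate number as a random block over root and shoot. Line effects share their wild type arrays, so their correlation was set beside simulated unchanged groups against the same wild type arrays (100 draws) and beside wild type arrays split 2 and 2. Group labels were also regrouped. Annotation and figures used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.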

Results

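Transcript levels were measured on 32 rice arrays, with 4 replicates in each of 8 groups. The groups were root and shoot of wild type Nipponbare and of 3 transgenic lines, first AGR1/7, then AGR1/8, and finally AGR3/8, which carry a barley alanine aminotransferase behind the OsANT1 promoter. Alanine aminotransferase interconverts alanine and 2-oxoglutarate with pyruvate and glutamate. All plants received 5 mM ammonium and were sampled at maximum tillering. Median intensity per array ran from 14.4 to 17.4 in root and from 14.1 to 17.8 in shoot. Between 48.4% and 51.7% of the probe sets of a root array and between 47.7% and 52.3% of those of a shoot array had an intensity under 16. Replicate 1 of root wild type stood apart, with a mean correlation of 0.937 to its own group against a median of 0.978 over the root arrays. It had the lowest quality weight in root (0.194). The ratio of the GAPDH control probe sets at the 3′ and 5′ ends moved with the root groups. It ran from 4.84 to 18.3 in wild type, 2.43 to 4.80 in AGR1/7, 6.76 to 57.0 in AGR1/8 and 2.54 to 4.68 in AGR3/8. The other controls did not share this pattern. The actin ratio overlapped among the root groups (4.99 to 5.58 in wild type, 4.75 to 5.99, 5.22 to 6.13 and 4.41 to 5.54 in the lines). The EF1a ratio was alike in AGR1/7 (0.20 to 0.33) and AGR1/8 (0.22 to 0.33) and lower in AGR3/8 (0.022 to 0.12).

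The first question was how roots of the transgenic lines differed from wild type roots, taken as the mean of the 3 lines. SUT1, a sucrose transporter of the phloem, rose by 1.19 ± 0.16 log2 (SE, adjusted p = 0.00086), from an intensity of 19.5 ± 6.19 (SD, n = 4) in wild type to 72.8 ± 10.5 in AGR1/8 and 76.2 ± 24.4 in AGR3/8. SAPK9, a protein kinase of the abscisic acid response, rose by 0.79 ± 0.10 log2 (adjusted p = 0.000525). CIPK10, a kinase partner of calcineurin B-like calcium sensors, rose on all 3 of its probe sets, by 1.10, 1.00 and 0.96 log2. HXK4, a hexokinase, rose by 0.47 ± 0.09 log2 (adjusted p = 0.00939), and BBD1 rose by 1.61 ± 0.20 log2 (adjusted p = 0.000404). GLN1-1, a cytosolic glutamine synthetase that fixes ammonium into glutamine, fell by 0.77 ± 0.13 log2 (adjusted p = 0.00515). Its intensity was 2050 ± 334 in wild type and 1159 ± 293, 1431 ± 175 and 1026 ± 51.2 in the 3 lines. The lignin pathway ligase 4CL-3 fell by 0.90 ± 0.08 log2 (adjusted p = 1.51e-05), the xylan-related glycosyltransferase GT43A fell by 1.21 ± 0.23 (adjusted p = 0.00882) and the acyltransferase AT7 by 1.26 ± 0.27 (adjusted p = 0.0176). DAHPS2, which begins the shikimate pathway, fell by 0.39 ± 0.07 log2 (adjusted p = 0.00996), and SCS-beta, a succinyl-CoA synthetase subunit, by 0.56 ± 0.11 (adjusted p = 0.00993). Each gene that rose was above the wild type mean on 12 of 12 transgenic arrays, and each that fell was above it on 0 of 12. These arrays come from 3 lines set against the same wild type mean, so they are not 12 independent replicates of the transgene. With the line as a random unit 137 root probe sets were called instead of 2027, and whether these genes were among them is not given here.

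The largest root changes were on probe sets without a descriptive gene name. An OsAffx probe set that matches no gene of the table rose by 6.48 ± 0.09 log2 (adjusted p = 4.75e-17), from 35.5 ± 8.37 in wild type to 4605 ± 555, 4261 ± 308 and 4793 ± 107. LOC4331398 rose by 5.74 ± 0.54 log2 (adjusted p = 1.75e-05), from 9.25 ± 3.96 to 2501 ± 150, 2193 ± 328 and 826 ± 831. Its second probe set gave 5.67 log2. LOC4340325 rose by 2.61 ± 0.10 log2 on average, through 3.41 in AGR1/8 and 4.24 in AGR3/8 against 0.17 in AGR1/7 (adjusted p = 0.457). LOC4350802 rose by 1.88 ± 0.12, of which AGR1/8 gave 5.04. LOC4341168 fell by 1.81 ± 0.29 log2 (adjusted p = 0.00354) and LOC4343487 fell by 1.57 ± 0.32 (adjusted p = 0.0129), both lower on 12 of 12 arrays.

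**Figure D1:**
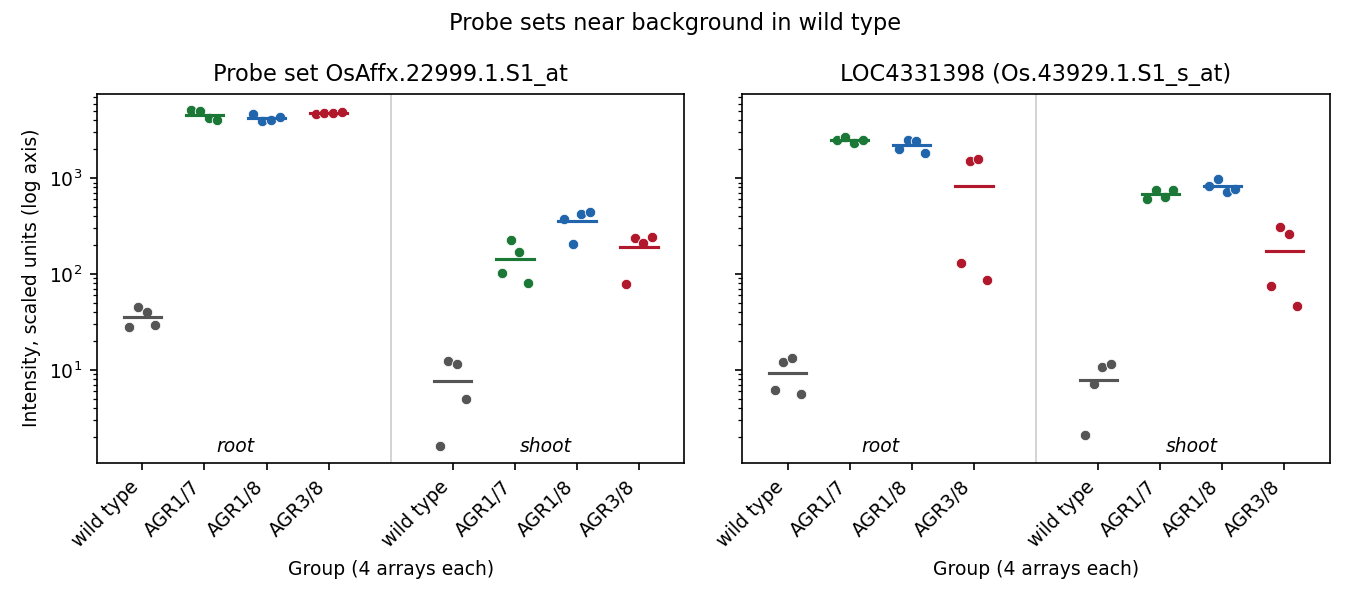
Intensity in scaled units (log axis) per array for probe sets low in wild type, by tissue and group with 4 arrays each; points are arrays. On the OsAffx probe set that matches no gene of the table the lowest wild type root lies at 27.8, and the transgenic roots lie between 3974 and 5100.

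Clock genes formed the only planned list that rose in root by camera. Of 8 circadian probe sets 4 rose and 0 fell (5 and 0 adjusted over the list alone). The median change was 0.31 log2 (camera adjusted p = 0.00098, and adjusted p = 0.174 with an estimated correlation). The latter became 0.0459 without root wild type 1, with 3 members called. The clock list also passed by fry (adjusted p = 0.000155). The pseudo-response regulators PRR95 (0.71 ± 0.11 log2, adjusted p = 0.0022) and PRR1 (0.67 ± 0.10, adjusted p = 0.0021) rose on 12 of 12 arrays, and PRR73 rose by 0.35 ± 0.07 (adjusted p = 0.0126, 12 of 12) on its first probe set. PRR95 went from 597 ± 141 in wild type to 982 ± 62.3, 972 ± 57.0 and 958 ± 83.6. The second PRR73 probe set, at 0.32 log2, lost its call without each of 6 arrays, root wild type 1 (adjusted p = 0.127) and 3, AGR1/8 2 and 3 and AGR3/8 2 and 3.

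By camera 5 planned lists fell in root, and all of them lost the call with an estimated correlation. By fry, which does not compare a list with other genes, the histone (adjusted p = 0.0458) and pathogenesis-related (0.0386) lists passed. The jasmonate (0.0728), P450 (0.0720) and auxin (0.194) lists did not pass by fry. The histone and cell cycle list held only MCM genes of the replicative helicase. Of its 8 probe sets 0 passed over all probe sets and 6 were lower adjusted over the list alone (median −0.64 log2, adjusted p = 0.00162, and adjusted p = 0.26 with an estimated correlation). The jasmonate and ethylene list had 1 member higher and 2 lower of 25 (2 and 13 adjusted over the list alone; median −0.29, adjusted p = 0.00098, and adjusted p = 0.31 with an estimated correlation; 0 lower without root wild type 1). Its higher member was GATA20, matched through an alias and known as a GATA zinc finger protein (0.43 ± 0.09 log2, adjusted p = 0.0121, 12 of 12 arrays). The pathogenesis-related list held chitinases only, 3 of 5 lower (3 adjusted over the list alone; median −0.64, adjusted p = 0.00906, and adjusted p = 0.26 with an estimated correlation). The chitinase LOC4351188 fell by 1.22 ± 0.30 log2 (adjusted p = 0.0295, lower on 12 of 12 arrays), and lost its call without root wild type replicate 3 (0.80 log2 lower, adjusted p = 0.0783) or 4. By line this chitinase was called only in AGR1/8, at −2.08 ± 0.36 log2, and the lines differed. It is thus in the set of AGR1/8 root changes whose grouping along the chromosomes is given further below. The P450 list had 1 member higher and 1 lower of 32 (2 and 1 adjusted over the list alone; median −0.22, adjusted p = 0.0172, and adjusted p = 0.26 with an estimated correlation). Its higher member, Cyp3, was matched by symbol alone and lost its call without root wild type 1, 3 (adjusted p = 0.0942) or 4, AGR1/8 1 or 3, or AGR3/8 3 or 4. Its lower member ABA8OX1, an abscisic acid hydroxylase, lost its call without root wild type 1 (adjusted p = 0.141) or 2, AGR1/8 2 or AGR3/8 3. The median of the P450 list was −0.11 without root wild type 3 and −0.12 without root wild type 4. Of 50 auxin, cytokinin and gibberellin probe sets 2 were lower, 1 of them adjusted over the list alone (median −0.08, adjusted p = 0.0428, and adjusted p = 0.348 with an estimated correlation). Without root wild type 1 only 1 was lower, and without root wild type 2 the median was −0.05. The list was not called with the replicate number as a block (adjusted p = 0.0759) or with array weights (0.189). The auxin response factor ARF9 fell by 0.33 ± 0.07 log2 (adjusted p = 0.0173, lower on 12 of 12 arrays). Without root wild type replicate 3 the pathogenesis-related list (adjusted p = 0.218) and the P450 list (adjusted p = 0.242) were not called. The auxin list lost its call under quantile normalization (0.0532) and without each of root wild type 1 (0.136) and 2 (0.273), AGR1/7 1 (0.0668) and 4 (0.0566), AGR1/8 2 (0.0588) and 3 (0.0519), and AGR3/8 1 (0.0733) and 4 (0.0537).

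The other planned lists were not called in root by camera. Of them only the WRKY, NAC, MYB, bHLH and bZIP list passed by fry (adjusted p = 0.0276). Ammonium, nitrate and urea transport had 0 of 13 probe sets past the threshold, also 0 adjusted over the list alone, with a median of 0.02 while the test pointed down (adjusted p = 0.827). The ammonium transporters AMT1-2 (0.62 ± 0.43 log2, adjusted p = 0.406), AMT1 (0.07 ± 0.23, adjusted p = 0.891) and AMT2-1 (−0.10 ± 0.11, adjusted p = 0.64) did not pass. The nitrogen assimilation list matched only Fd-GOGAT, the ferredoxin-dependent glutamate synthase, and TPP2, a name not known to belong there. It had 0 of 5 past the threshold and 0 adjusted over the list alone (adjusted p = 0.655), and Fd-GOGAT stood at 0.11 ± 0.07 log2 (adjusted p = 0.382). Aquaporins had 1 member higher and 1 lower of 28 (2 and 1 adjusted over the list alone; adjusted p = 0.92; median 0.01, mean −0.01). Heat shock proteins had 1 higher of 35 (0 adjusted over the list alone; adjusted p = 0.655), and metal homeostasis 1 lower of 30 (1 higher and 1 lower adjusted over the list alone; adjusted p = 0.655). Phosphate transport had 0 of 11 (0 adjusted over the list alone; adjusted p = 0.757). Redox enzymes had 1 lower of 12 (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.92; median 0.02, mean −0.35). The WRKY, NAC, MYB, bHLH and bZIP list had 4 higher of 50 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.208), and it was called upward without root wild type replicate 1 (adjusted p = 0.0341, and adjusted p = 0.329 with an estimated correlation) and with array weights (0.0406, and adjusted p = 0.160 with an estimated correlation). Without that array it had 2 higher, the aquaporin, heat shock and metal lists had no member past the threshold, and the medians of the nitrogen transport and redox lists were −0.09 and −0.06.

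Among the 18 lists by symbol, chosen after the data had been seen, 5 fell in root and 0 rose by camera. By fry the cell wall (adjusted p = 0.0317) and phenylpropanoid (0.0208) lists passed. The defence (0.0712), cell cycle (0.184) and ribosomal (0.181) lists did not pass by fry. In the cell wall list 23 of 104 probe sets fell and 0 rose, with a median of −0.46 log2 (45 lower and 2 higher adjusted over the list alone; adjusted p = 3.03e-16, and adjusted p = 0.216 with an estimated correlation). GT43A belonged to it, and so did the cellulose synthase CESA6, which fell by 1.04 ± 0.23 log2 (adjusted p = 0.0206, lower on 12 of 12 arrays) and lost its call without root wild type replicate 1 (adjusted p = 0.0690). Without that array 7 cell wall members fell and the median was −0.25. Phenylpropanoid and flavonoid genes had 1 higher and 9 lower of 44 (2 and 15 adjusted over the list alone; median −0.26, adjusted p = 1.69e-06, and adjusted p = 0.216 with an estimated correlation), among them 4CL-3 and AT7. They had 0 higher and 5 lower without root wild type 1. Defence proteins had 7 lower of 56 (2 higher and 9 lower adjusted over the list alone; median −0.18, adjusted p = 0.000514, and adjusted p = 0.216 with an estimated correlation), and 4 without that array. Cell cycle genes (1 higher, 2 lower of 110; median −0.19, adjusted p = 2.33e-05) and ribosomal proteins (1 lower of 38; median −0.15, adjusted p = 7.04e-06) were called as lists with few members past the threshold (0 adjusted over the list alone), and both had an adjusted p = 0.503 with an estimated correlation. Without root wild type 1 neither had a member past the threshold, and their medians were −0.13 and −0.10. Not called were calcium signalling (5 higher, 6 lower of 97; adjusted p = 0.0539), sugar transport and metabolism (6 higher, 4 lower of 108; 0.0577), nitrogen assimilation (1 lower of 30, which was GLN1-1; 0.655), amino acid synthesis (1 higher, 3 lower of 34; 0.511), cytokinin signalling (1 and 1 of 34; 0.994) and diterpenoid precursors (0 of 22; 0.252). Potassium transport (2 higher of 30) and glycolysis (1 higher, 2 lower of 53) both had an adjusted p of 0.511. Phosphate regulators (0 of 26; 0.994), photosynthesis (1 lower of 35; 0.789), redox proteins (3 higher, 2 lower of 87; 0.878), small heat shock proteins (2 higher of 58; 0.324) and stress regulators (4 higher, 3 lower of 121; 0.994) were not called either. Adjusted over the list alone the counts were 5 and 7 for calcium, 10 and 13 for sugar, 2 and 3 for amino acids, 5 and 3 for redox proteins, 1 and 0 for small heat shock proteins and none for photosynthesis, and the others were the same. The calcium list was called without root wild type 2 (0.0368), 3 (0.0323) or 4 (0.0207), AGR1/8 1 (0.0495), 2 (0.0463) or 3 (0.0442), or AGR3/8 1 (0.0422). The sugar list was called without root wild type 2 (0.0357) or 4 (0.0329) or AGR1/8 1 (0.0495), and the diterpenoid list without root wild type 1 (1.3e-05), which took its median from −0.09 to −0.65 log2, beyond that of the cell wall list. Without root wild type 1 the members past the threshold were 5 higher and 2 lower for calcium, 2 and 2 for sugar, 1 and 0 for stress regulators, 2 and 0 for redox proteins, 0 and 1 for glycolysis, 1 and 0 for small heat shock proteins, and none for potassium and cytokinin. With the replicate number as a block the calcium (0.0435) and sugar (0.0462) lists were called. None of the root calls gained under a setting held with an estimated correlation (lowest adjusted p = 0.118; 0.367 for the diterpenoid list without root wild type 1).

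**Figure D2:**
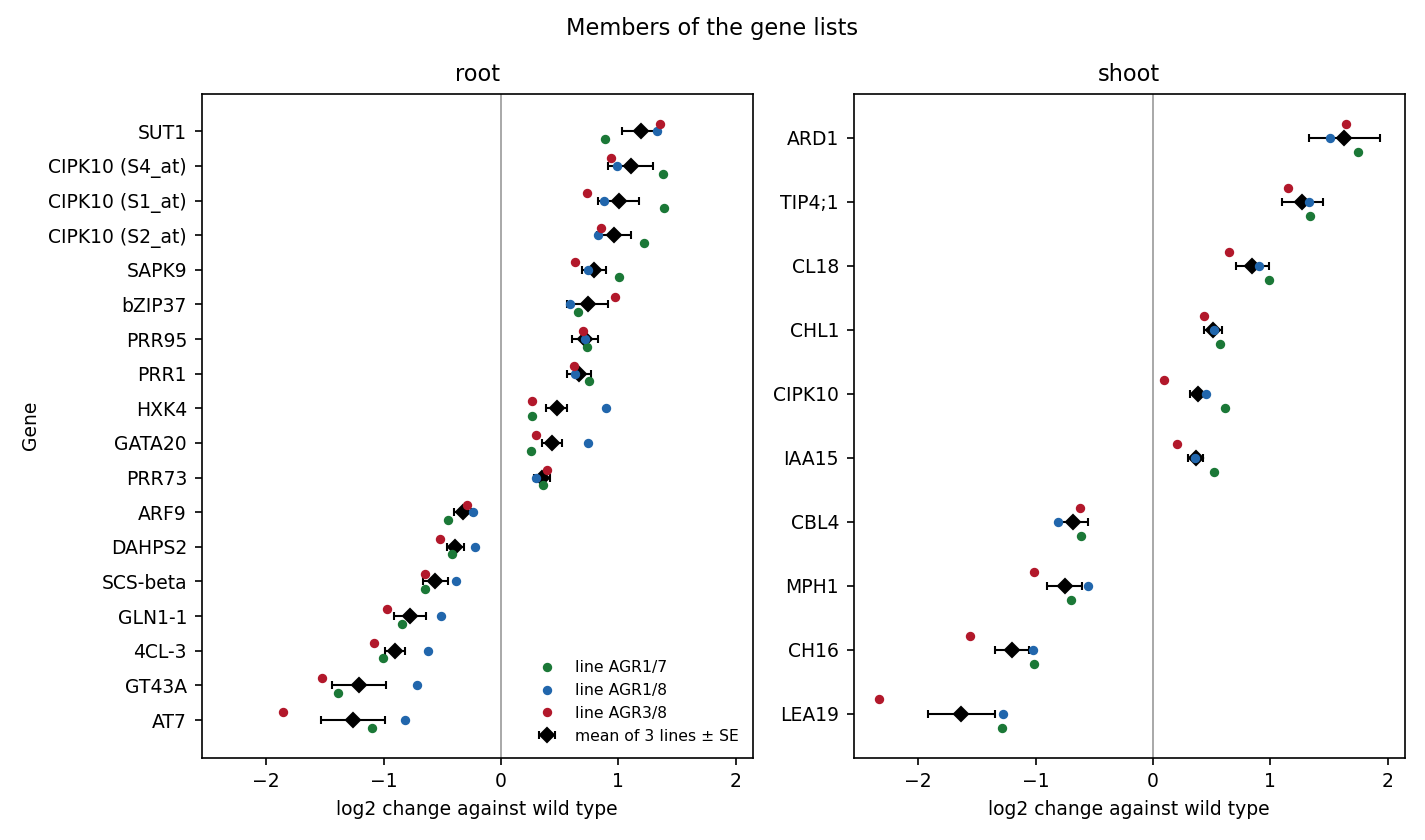
Change against wild type in log2 units for list members with a descriptive name whose call held without any single array, in root and shoot; diamonds are the mean of the 3 lines ± SE and small points the single lines. SUT1 stands at 1.19 and AT7 at −1.26 in root, TIP4;1 at 1.27 and LEA19 at −1.63 in shoot.

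Over the root transcriptome 2027 of 38129 probe sets differed between the transgenic mean and wild type, 1250 higher and 777 lower, by limma. Of these 1961 had the same sign in all 3 lines. Only 197 changed by at least 1 log2, 77 of them higher and 120 lower, the reverse of the overall split. With the line as a random unit 137 were called, without the filter on dim probe sets 1268 and in a single fit of all 32 arrays 3881. Single arrays moved the count by more than 1.5 times. It was 783 without wild type 1, with 679 of the original calls kept, and 1083 without wild type 3. It was 1286 without AGR1/8 2, and 1235, 1226 and 1280 without AGR3/8 2, 3 and 4.

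Roots of each line were then compared with wild type roots. In AGR1/7, 940 probe sets differed (578 higher, 362 lower). LOC9268613 rose there by 2.53 ± 0.20 log2 (adjusted p = 1.2e-05), from 7.78 ± 3.57 to 124 ± 40.8, against 0.18 and 0.22 in the other lines, and the lines differed (adjusted p = 1.17e-06). In AGR1/8, 944 differed (475 higher, 469 lower), a split that turned under most settings (402 higher and 525 lower without wild type 1, 567 and 666 with array weights). By at least 1 log2 376 differed, 157 higher and 219 lower. LOC4334900 rose there by 5.12 ± 0.15 log2, from 4.50 ± 2.89 to 696 ± 78.8, and LOC4342656 fell by 2.88 ± 0.20 log2, from 337 ± 69.0 to 33.5 ± 18.0. In AGR3/8, 2064 differed (1222 higher, 842 lower), and more were lower than higher at a change of at least 1 log2 (252 against 120) and under median centring (942 against 865). An Os probe set that matches no gene of the table rose there by 4.28 ± 0.13 log2, from 0.925 ± 0.900 to 318 ± 67.9. LOC4343487 fell by 2.64 ± 0.39 and LOC4325938 fell by 2.39 ± 0.43. The AGR1/7 count was 594 without wild type 1, 429, 386 and 392 without its own replicates 1, 3 and 4, and 599, 584, 612 and 613 without AGR3/8 1, 2, 3 and 4. The AGR3/8 count was 1241, 3546 and 972 without wild type 1, 2 and 3, 3442 without AGR1/7 1, and 1064, 574, 428 and 729 without its own replicates 1 to 4.

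In root 119 probe sets were called in the same direction in all 3 lines, 95 higher and 24 lower, where independent calls would give 0.231 and 0.0983. BBD1 was among them, at 1.78, 1.46 and 1.58 log2. All lines share the wild type arrays, so overlap is expected without a shared effect. The mean correlation of the line effects across probe sets was 0.598 against 0.641 for simulated unchanged groups with the same wild type arrays, with a covariance of 0.0709 against 0.0369. By pair of lines, the covariance was within the simulated range for AGR1/7 with AGR1/8 (0.0577, upper limit 0.0851) and AGR1/8 with AGR3/8 (0.0716, 0.0821) and above it for AGR1/7 with AGR3/8 (0.0834, 0.0732). With the wild type arrays split 2 and 2 the mean correlation was 0.261 and the mean covariance 0.0373. The F test among the lines called 1139 probe sets, among them HXK4 (0.27, 0.89 and 0.27 log2; adjusted p = 0.00299) and GATA20 (0.26, 0.74 and 0.30; adjusted p = 0.0218). The test of GLN1-1 among lines did not pass (adjusted p = 0.253). The F count was 2134 without wild type 1, 736 without AGR1/8 1 and 748 without AGR1/8 4. The count in all 3 lines was 255 and 78 without wild type 2 and 3, 69 and 75 without AGR1/7 3 and 4, 71, 62, 69 and 75 without AGR1/8 1 to 4, and 75, 68, 66 and 73 without AGR3/8 1 to 4.

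**Figure D3:**
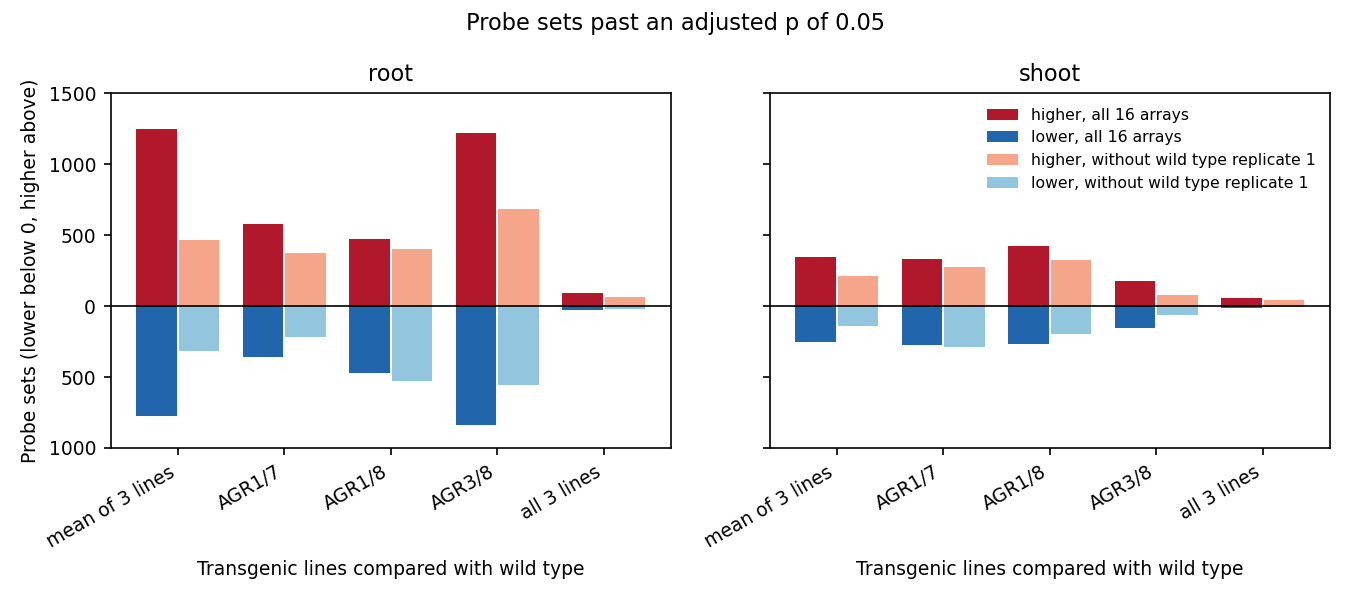
Number of probe sets past an adjusted p of 0.05 against wild type, higher above 0 and lower below 0, for the mean of the 3 lines, each line and all 3 lines in the same direction; dark bars use all 16 arrays of a tissue and light bars leave out wild type replicate 1. For the transgenic mean the root total goes from 2027 to 783 and the shoot total from 599 to 354.

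The same question was asked of the shoot. TIP4;1, a tonoplast aquaporin, rose by 1.27 ± 0.17 log2 (adjusted p = 0.000602), from 862 ± 281 in wild type to 2102 ± 173, 2110 ± 371 and 1874 ± 438. CHL1, a subunit of the magnesium chelatase of chlorophyll synthesis, rose by 0.51 ± 0.07 (adjusted p = 0.00118), and CL18, a chloroplast ribosomal protein, by 0.85 ± 0.14 (adjusted p = 0.0036). ARD1, an acireductone dioxygenase of the methionine salvage cycle, rose by 1.63 ± 0.30 (adjusted p = 0.00738; above the wild type mean on 11 of 12 arrays). The auxin response repressor IAA15 rose by 0.36 ± 0.07 (adjusted p = 0.00654), and CIPK10 rose by 0.39 ± 0.07 on 1 of its probe sets (adjusted p = 0.00762, 11 of 12 arrays). LEA19, a late embryogenesis abundant protein, fell by 1.63 ± 0.29 log2 (adjusted p = 0.00523), from 236 ± 103 to 84.9 ± 31.6 in AGR1/7 and 37.9 ± 36.4 in AGR3/8. CH16, on the chitinase list, fell by 1.20 ± 0.14 (adjusted p = 0.000123), the MYB factor MPH1 by 0.75 ± 0.15 (adjusted p = 0.0116) and the calcium sensor CBL4 by 0.68 ± 0.13 (adjusted p = 0.0102). Apart from ARD1 and CIPK10, each of these was on its side of the wild type mean on 12 of 12 arrays.

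The largest shoot changes included the same pair of probe sets as in root. LOC4331398 rose by 4.24 ± 0.29 log2 (adjusted p = 1.65e-07), from 7.83 ± 4.23 to 686 ± 77.0, 826 ± 118 and 174 ± 132, and the unmatched OsAffx probe set rose by 3.25 ± 0.26 (adjusted p = 1.28e-06), from 7.63 ± 5.20 to 145 ± 66.4, 361 ± 107 and 193 ± 77.8. LOC4335304 rose by 2.30 ± 0.17 log2 (adjusted p = 3.99e-07), from 4.45 ± 0.83 to 39.6 ± 14.4, 105 ± 24.9 and 146 ± 48.1, and its other probe sets by 2.35 and 2.17. LOC4334015 fell by 1.74 ± 0.26 (adjusted p = 0.00118), LOC4333648 by 1.68 ± 0.16 (adjusted p = 1.84e-05) and LOC4334013 by 1.49 ± 0.26 (adjusted p = 0.00434). All were on their side of the wild type mean on 12 of 12 arrays.

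Of the planned lists 4 fell in shoot and 0 rose by camera. By fry the transcription factor (adjusted p = 0.00412), nitrogen transport (0.0385) and water deficit (0.0385) lists passed, and the jasmonate list did not (0.225). The WRKY, NAC, MYB, bHLH and bZIP list had 1 lower of 42, which was MPH1 (1 adjusted over the list alone). Its median was −0.11 log2, and it was the only list whose call held with an estimated correlation (adjusted p = 0.00254, and adjusted p = 0.0297 with an estimated correlation). The latter was above 0.05 without shoot wild type 1 (0.0528) or 2 (0.0611), under median centring (0.132), with array weights (0.0594), with the replicate block (0.0648) and in the fit of all 32 arrays (0.155). Ammonium, nitrate and urea transport had 1 lower of 13 (1 adjusted over the list alone; median −0.12, adjusted p = 0.0295, and adjusted p = 0.155 with an estimated correlation), and its median was −0.20 without shoot wild type 4. Its member AMT1, an ammonium transporter, fell by 0.31 ± 0.07 (adjusted p = 0.0262, lower on 11 of 12 arrays). Its intensity was 970 ± 55.9 in wild type and 623 ± 27.7, 789 ± 85.0 and 958 ± 65.6 in AGR1/7, AGR1/8 and AGR3/8, and the lines differed (adjusted p = 0.00295). AMT1 lost its call without shoot wild type 1 (adjusted p = 0.0870), 2 (0.108) or 3. The water deficit list, LEA19 and RAB dehydrins, had 1 lower of 5 (2 adjusted over the list alone; median −0.41, adjusted p = 0.00663, and adjusted p = 0.155 with an estimated correlation). The jasmonate and ethylene list had 0 of 25 past the threshold (0 adjusted over the list alone; median −0.23, adjusted p = 0.00663, and adjusted p = 0.341 with an estimated correlation). Without shoot wild type 1 the water deficit list (0.0658), the nitrogen transport list (0.0658) and the jasmonate list (0.457) were not called, with medians of −0.22, −0.10 and −0.09, and without shoot wild type 3 the nitrogen transport list was not called (0.0840). The jasmonate median was −0.15 without AGR1/7 4. With array weights the nitrogen transport (0.0602) and jasmonate (0.0772) lists were not called, and in the fit of all 32 arrays the former was not (0.105).

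The other planned lists were not called in shoot. Aquaporins had 1 higher and 1 lower of 26 (2 and 4 adjusted over the list alone; adjusted p = 0.765), with a median of 0.00 while the test pointed down. The circadian list had 1 lower of 8 (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.664). Nitrogen assimilation had 0 of 5 (0 adjusted over the list alone; adjusted p = 0.368), with Fd-GOGAT at 0.18 ± 0.12 log2 (adjusted p = 0.574). Auxin, cytokinin and gibberellin genes had 1 higher of 43, IAA15 (1 adjusted over the list alone; adjusted p = 0.415). Heat shock proteins had 3 higher of 38 (3 higher and 2 lower adjusted over the list alone; adjusted p = 0.415). Cytochromes P450 (31 probe sets; adjusted p = 0.141), the MCM genes (5; 0.134), metal homeostasis (31; 0.664), phosphate transport (11; 0.124) and redox enzymes (10; 0.124) had 0 past the threshold, and 0 adjusted over the list alone. Without shoot wild type 1 the heat shock and circadian lists had no member past the threshold. The P450 list was called without AGR1/7 3 (0.0429, and adjusted p = 0.222 with an estimated correlation), the phosphate list without shoot wild type 1 (0.0118, and adjusted p = 0.265 with an estimated correlation) and the redox list without shoot wild type 2 (0.0242, and adjusted p = 0.159 with an estimated correlation) or AGR3/8 1 (0.0478, and adjusted p = 0.293 with an estimated correlation).

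Of the lists by symbol, chosen after the data had been seen, 2 rose and 6 fell in shoot, and none of these calls held with an estimated correlation. Without the dim filter the calls of stress, defence and calcium genes did (all 0.0322), as did those of stress and defence genes without shoot wild type 4 (both 0.0460). By fry the stress (adjusted p = 0.0210), defence (0.0210) and calcium (0.0255) lists passed in the full fit. The other lists called by camera did not pass by fry (lowest adjusted p = 0.0615, for ribosomal proteins). Photosynthesis genes had 4 higher and 0 lower of 40 (the same adjusted over the list alone), with a median of 0.25 log2 (adjusted p = 1.18e-06, and adjusted p = 0.283 with an estimated correlation). Under quantile normalization this call was lost (median 0.01, adjusted p = 0.483), while its 4 members were still called. The signal of the arrays differed along with this list. Shoot AGR3/8 2 and 3 had the highest mean of the photosynthesis genes (10.9 and 10.8 log2), the highest mean intensities (213 and 208) and actin 3′ to 5′ ratios of 9.12 and 12.4, and shoot wild type 1 had the lowest mean of these genes (10.2) and the lowest mean intensity (158). The called members belong to chlorophyll synthesis: CHL1, the chlorophyll synthase CHLG (0.47 ± 0.09 log2, adjusted p = 0.00704, 12 of 12 arrays), the protochlorophyllide reductase PORA (0.70 ± 0.15, adjusted p = 0.0209, 12 of 12) and GSA. CHLG lost its call without shoot wild type 3 (adjusted p = 0.0556), and PORA without shoot wild type 1 (0.0514) or 2 (0.113). GSA lost its call without any of 13 single arrays, all but AGR1/7 1, AGR1/8 3 and AGR3/8 1 (at most 0.186, without shoot wild type 3), and under median centring (0.0801). Without shoot wild type 1, 2 members of the list were called. Ribosomal proteins had 2 higher of 38, CL18 and rpl5 (18 adjusted over the list alone; median 0.23, adjusted p = 9.01e-14, and adjusted p = 0.197 with an estimated correlation), and rpl5 lost its call without shoot wild type 2 or 3 (0.113). Stress regulators had 8 lower of 118 (16 adjusted over the list alone; median −0.10, adjusted p = 1.41e-06, and adjusted p = 0.103 with an estimated correlation) and defence proteins 1 lower of 58, CH16 (1 adjusted over the list alone; median −0.17, adjusted p = 1.84e-05, and adjusted p = 0.103 with an estimated correlation). Without shoot wild type 1 the stress list had 3 lower and a median of −0.06, and the defence list a median of −0.10. Calcium signalling had 2 higher and 2 lower of 96 (6 and 16 adjusted over the list alone; adjusted p = 0.00256, and adjusted p = 0.111 with an estimated correlation). Phosphate regulators had 0 of 24 (0 adjusted over the list alone; 0.00521, and adjusted p = 0.197 with an estimated correlation), diterpenoid precursors 0 of 21 (2 lower adjusted over the list alone; 0.0157, and adjusted p = 0.369 with an estimated correlation) and phenylpropanoid genes 2 lower of 42 (3 adjusted over the list alone; 0.025, and adjusted p = 0.409 with an estimated correlation). The calcium list was not called without shoot wild type 1 (0.0796; 1 higher and 3 lower), the phosphate list without wild type 3 (0.0542) and the diterpenoid list without AGR3/8 1 (0.0509). The phosphate median went from −0.16 to −0.26 without wild type 1 and to −0.07 without wild type 3. The phenylpropanoid list was not called without wild type 1 (0.487; 0 lower, median −0.03 against −0.12), AGR1/8 2 (0.0536) or AGR3/8 1 (0.0767).

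The other lists by symbol were not called in shoot. Amino acid synthesis (1 lower of 35) and cell cycle (0 of 96) both had an adjusted p of 0.971. Cell wall (0 of 87; 0.0686), cytokinin signalling (0 of 34; 0.0855), glycolysis (0 of 51; 0.335), nitrogen assimilation (0 of 29; 0.895) and potassium transport (0 of 31; 0.0839) had no member past the threshold. Redox proteins (1 lower of 90; 0.16), small heat shock proteins (2 higher of 62, ARD1 and HSP18.0; 0.5) and sugar genes (1 lower of 109; 0.104) had few. ARD1, the acireductone dioxygenase named above, entered the heat shock list through a symbol or alias. Adjusted over the list alone small heat shock proteins had 2 higher and 3 lower, and the other counts were the same. HSP18.0 lost its call without shoot wild type 1, 2 or 3 (0.150), AGR1/7 2 or 4, AGR1/8 2 or 4 or AGR3/8 3. The cell wall list was called without shoot wild type 2 (0.0223) or 4 (0.0328), AGR1/7 1 (0.0351) or AGR3/8 4 (0.0406), the cytokinin list without wild type 1 (0.0444), the potassium list without wild type 4 (0.0199) and the redox list without AGR3/8 1 (0.0440). None of these held with an estimated correlation (lowest adjusted p = 0.0510, for potassium; 0.339 for cytokinin). Without wild type 1 the amino acid and redox lists had no member past the threshold and the small heat shock list 1.

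In shoot 599 of 38129 probe sets differed between the transgenic mean and wild type, 348 higher and 251 lower, by limma, and 591 had the same sign in all 3 lines. The count was 354, 291 and 224 without wild type 1, 2 and 3, and 1026 without AGR3/8 1. Of the 599, 306 were still called without wild type 1. Without the filter on dim probe sets 385 were called, without the intensity trend 318, with array weights 997 and with the line as a random unit 115. Under median centring 256 were higher and 263 lower.

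By line, 609 shoot probe sets differed in AGR1/7 (333 higher, 276 lower), 693 in AGR1/8 (423 and 270) and 331 in AGR3/8 (174 and 157). Under median centring the split was turned in AGR1/7 (208 higher, 388 lower) and AGR3/8 (99 and 155). It was also turned in AGR1/7 without wild type 1 (276 and 289), in AGR1/8 without its own replicate 1 (468 and 515) and in AGR3/8 without its own replicate 4 (97 and 108) or AGR1/8 1 (130 and 132) or 4 (108 and 112). LOC4340240 rose in AGR1/7 alone among the calls, by 2.05 ± 0.12 log2 (adjusted p = 3.8e-08), from 291 ± 47.0 to 1253 ± 156, against −0.01 and −0.40 in the other lines, and the lines differed (adjusted p = 1.23e-09). LOC4328727 fell in AGR1/7 by 1.44 ± 0.22 (adjusted p = 0.0016). LOC4334900 rose in AGR1/8 by 4.69 ± 0.57 (adjusted p = 0.00025), as it did in root, and LOC4345561 fell there by 1.82 (adjusted p = 0.0015). The unmatched Os probe set named for AGR3/8 roots rose in AGR3/8 shoots by 4.96 ± 0.21 (adjusted p = 1.8e-10), also as in root. LEA19 fell by 2.34 there and LOC4334015 fell by 2.40. The AGR1/7 count was 341 and 311 without wild type 2 and 3, and 380 and 370 without its own replicates 3 and 4. The AGR1/8 count was 348 and 294 without wild type 2 and 3, and 230 and 259 without its own replicates 2 and 4. The AGR3/8 count was 144, 117 and 133 without wild type 1, 2 and 3, 217 without AGR1/7 4, 213 and 220 without AGR1/8 3 and 4, and 1413, 121, 107 and 205 without its own replicates 1 to 4.

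In shoot 70 probe sets were called in the same direction in all 3 lines, 55 higher and 15 lower (32 and 15 under median centring), where independent calls would give 0.0169 and 0.00805. LOC4331398 led those that match a gene, followed by 2 probe sets of LOC4335304 and by LOC4334015, which was not called in AGR1/7 (0.0638) or AGR1/8 (0.0749) without wild type 1. The mean correlation of line effects was 0.503 against 0.497 for simulated unchanged groups, the covariance 0.0357 against 0.0203, and the correlation with wild type arrays split 2 and 2 was 0.192. By pair, the covariance was within the simulated range for AGR1/7 with AGR3/8 (0.0310, upper limit 0.0325) and above it for AGR1/7 with AGR1/8 (0.0381, 0.0330) and AGR1/8 with AGR3/8 (0.0379, 0.0294). The F test among lines called 860 probe sets. AMT1 was 1 of them, at −0.63, −0.30 and −0.02 log2. The count in all 3 lines was 38 and 27 without wild type 2 and 3, 44 without AGR1/7 4, 45 and 40 without AGR1/8 2 and 4, and 121, 46, 35 and 38 without AGR3/8 1 to 4. The F count was 502, 363 and 547 without AGR1/7 1, 3 and 4, 413, 488 and 389 without AGR1/8 2, 3 and 4, and 1773, 257 and 278 without AGR3/8 1, 2 and 3.

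Wild type root and shoot were compared as a check of the tissues. The silicon exporter Lsi2 was higher in root by 8.11 ± 0.10 log2 (adjusted p = 2.8e-32), at 4759 ± 945 against 0.975 ± 0.465. The Rubisco activase gene rcaA1 was lower in root by 8.48 ± 0.21 log2, at 9.20 ± 3.82 against 8952 ± 874, and ADI1 by 8.95 ± 0.21. LOC4329797 and LOC4332925 were higher in root by 8.10 ± 0.17 and 7.53 ± 0.21. In all, 22566 of 38129 probe sets differed, 12171 higher and 10395 lower in root.

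The last question was whether the transgenic effect differed between root and shoot. Opposite or unequal effects were tested as the root effect minus the shoot effect. LOC4335304 rose in shoot but stood at 0.01, −0.29 and −0.38 log2 in root, and the difference passed on its 3 probe sets (−2.28 ± 0.22, −2.64 ± 0.29 and −2.56 ± 0.34). The unmatched OsAffx probe set rose more in root (difference 3.23 ± 0.30, adjusted p = 4.0e-07), while the difference for LOC4331398 did not pass (adjusted p = 0.222). LOC4334015 differed by 2.60 ± 0.43 (adjusted p = 0.0012), with a root effect of 0.86 against −1.74 in shoot. The effect on SUT1 was greater in root (difference 1.17 ± 0.20, adjusted p = 0.00231), with 0.02 in shoot. The differences for TIP4;1 (−1.02, adjusted p = 0.0137), CL18 (−1.04, adjusted p = 0.00318) and CHLG (−0.75, adjusted p = 0.00674) passed, and their root effects of 0.25, −0.19 and −0.28 did not. The differences for GLN1-1 (−0.60, adjusted p = 0.0557) and AMT1 (0.39, adjusted p = 0.452) did not pass.

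Planned lists whose effect differed between tissues were the circadian list (root above shoot, adjusted p = 0.0108, and adjusted p = 0.201 with an estimated correlation), the WRKY, NAC, MYB, bHLH and bZIP list (root above shoot, 0.0106, and adjusted p = 0.0513 with an estimated correlation) and the MCM genes (root below shoot, 0.0167, and adjusted p = 0.455 with an estimated correlation). Of the lists by symbol, root lay below shoot for cell wall (6.62e-11, and adjusted p = 0.269 with an estimated correlation), ribosomal proteins (5.09e-18, and adjusted p = 0.269 with an estimated correlation), cell cycle (7.95e-05, and adjusted p = 0.361 with an estimated correlation), photosynthesis (0.000242, and adjusted p = 0.361 with an estimated correlation) and phenylpropanoid genes (0.0447, and adjusted p = 0.521 with an estimated correlation). It lay above shoot for stress regulators (0.00241, and adjusted p = 0.281 with an estimated correlation).

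Across 38129 probe sets 745 had a different transgenic effect in the tissues, 441 with the root effect above and 304 below. At a difference of at least 1 log2 80 were above and 98 below, and without root wild type 1 157 and 164. The count was 321 and 1606 without root wild type 1 and 2, and 338, 313 and 478 without shoot wild type 2, 3 and 4. Among 34190 probe sets tested in both tissues, 67 were higher in the transgenic mean of both, against 11.0 for independent calls, and 16 were lower in both, against 4.38. In opposite directions 8 were higher in root and lower in shoot, and 3 the reverse. The largest overlap of a single line was in AGR1/8, with 110 higher (5.01) and 56 lower (3.02) in both tissues. Root and shoot calls need not be independent. The deviations of wild type replicate 1 correlated between the tissues (r = 0.246). Large root changes called in AGR1/8 alone recurred in AGR1/8 shoots (r = 0.875). An excess over independent calls therefore does not by itself show a shared effect of the transgene.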

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

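The tests of the single root wild type array and of the probe sets low in wild type were chosen only after those results were seen, and so were the rules that leave the test of neighbouring genes undecided for small gene sets or where random sets give fewer than 1 pair on average. All patterns below were found and tested on the same arrays and stand as hypotheses.

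Root wild type replicate 1 stood apart from the other root wild type arrays, with a mean correlation of 0.937 to its own group. A transgenic sample under a wild type label was excluded, because a reporter control probe set that was high on every transgenic array had an intensity of 17.8 on it, against 4869 on the lowest transgenic root array. Green tissue in the root sample was excluded as well, since the photosynthesis genes by symbol had a mean of 5.95 log2 on it against a highest mean of 6.16 on the other root wild type arrays. Its deviation correlated across probe sets, which are not independent replicates, with that of shoot wild type replicate 1 (r = 0.246, against at most 0.103 for wild type pairs with different numbers and 0.117 for the other equal numbers), so a state of plant or handling shared by the 2 samples may be the source. Which state it was stays open, and no biological explanation was tested.

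Wild type arrays were low and transgenic arrays higher on a reporter control probe set and on the OsAffx probe set that matches no gene of the table, although shoot wild type 4 had an intensity of 99.6 on the former against at most 1.7 on the other shoot wild type arrays. On both, 24 of 24 transgenic arrays lay above all wild type arrays of their tissue by more than 1 log2, and 21 above those of both tissues, but the probe sets were picked for this, so it decides nothing about hybridisation to sequence brought in with the transgene. Scaling between arrays was excluded, since the root effect of the OsAffx probe set was 6.46 log2 after quantile normalization. That probe set was brighter in root than in shoot by at least 3.56 log2 in each line. A sequence driven by a promoter active mostly in root could give this. For the reporter probe set the root minus shoot difference was −0.71 log2 in AGR1/8, but 0.69 in AGR1/7 and 0.89 in AGR3/8. The rule, written after the values were seen, let a single line speak against such a promoter, and AGR1/8 met it. The other lines went the other way, so this test cannot decide about a promoter for the reporter probe set. Which sequence each of them detects, of the transgene or not, stays open, and induction of a rice gene was not tested.

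Root changes of at least 1 log2 that were called in AGR1/8 but in no other line, on probe sets that differed among lines, covered 268 probe sets (89 higher, 179 lower), and the 107 genes with a known order among them formed 71 pairs at most 10 genes apart. Random gene sets of that size gave a mean of 6.88 pairs (upper limit of the test 12), and sets of genes that differ between root and shoot gave 6.93 (upper limit 13). Both gave a one-sided permutation p of 1e-04, the smallest that 10000 draws can give. The genes that differ between root and shoot were 6364 of 16410 tested, and sets drawn from them paired like random sets. They cannot show how a small set of genes that change together is grouped, so the grouping that any set of changed genes shows stays open. In AGR3/8 23 such genes formed 1 pair (random mean 0.302) and in AGR1/7 6 genes formed 0 pairs, too few to decide. Across the 246 of these probe sets tested in shoot, the AGR1/8 root changes correlated with the AGR1/8 shoot changes at r = 0.875, against 0.147 with AGR3/8 and 0.0583 with AGR1/7 shoot changes. The probe sets were picked for having no root call in the other lines, so low values for those lines are partly set by the choice. The pairs lay on 9 chromosomes, 38 of them on chromosome 11 and 11 on chromosome 1, so no single stretch holds them all, though several stretches that differ in AGR1/8 may be the source, and sequence differences from the probes stay open, since other probe sets of the same genes were called the same way in 34.8% of cases (16 of 46) against 44.9% (31 of 69) for genes called by at least 1 log2 in AGR3/8 (two-sided Fisher's exact p = 0.335).

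The reporter control probe set took no part in the comparisons. Its intensity in root was 6181 ± 398, 4976 ± 98.1 and 5994 ± 337 (SD, n = 4) in AGR1/7, AGR1/8 and AGR3/8, against 13.98 ± 8.996 in wild type. In shoot it was 3835 ± 379, 8169 ± 1005 and 3291 ± 813, against 25.8 ± 49.2. In each tissue the two-sided exact permutation p was 0.000549, the smallest that 1820 splits can give, and 0.0352 adjusted over the 64 reporter probe sets. The highest group mean among the other 63 was 46.1 in root and 32.03 in shoot, and 0 of them passed after adjustment. Besides the reporter and the unmatched OsAffx probe set above, LOC4331398 was the only 1 of 57381 probe sets on which all transgenic arrays lay more than 1 log2 above all wild type arrays in both tissues, and 0 lay below.

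Several differences between the root and shoot effects were large (limma, root minus shoot). The OsAffx probe set of the pattern above differed by 3.23 log2, LOC4334015 by 2.60 and LOC4335304 by −2.64, −2.56 and −2.28 on its probe sets. Another OsAffx probe set that matches no gene differed by −2.08 (adjusted p = 0.000295), with −2.26 in root and −0.17 in shoot. LOC107277838 differed by 2.18 (adjusted p = 0.0327), and the call was lost without root wild type 1 (0.0667) or 4. Its root group means were only 2.05 to 5.375, and its shoot wild type mean was 289 ± 450. An Os probe set that matches no gene differed by 2.14 (adjusted p = 0.0292), and the call was lost without root wild type 1 (0.0765) or 3 or shoot wild type 1, 2 or 3. Its shoot group means were only 3.65 to 8.475. LOC4325264 differed by −2.16 (adjusted p = 0.0384), lost without root wild type 1 (0.123), root AGR3/8 2 or 3, any shoot wild type array or shoot AGR1/7 3. LOC4339960 differed by 1.98 (adjusted p = 0.0434), and this call was lost without any of 17 single arrays. They were root wild type 1 (0.131), root AGR1/8 2 or 3, root AGR3/8 2 or 3, each shoot wild type array, shoot AGR1/7 2, 3 or 4, shoot AGR1/8 2, 3 or 4 and shoot AGR3/8 3 or 4. In all 745 probe sets differed between the tissues, 56 of them among those named for a single tissue, while 1139 root and 860 shoot probe sets differed among the lines.

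In groups of 4 arrays, an array was singled out where its gap to the nearest other exceeded Dixon's critical value, which chance gives in about 5% of groups. Over 48 groups of array measures this met the mean correlation to the own group of root AGR1/7 1 (0.961), shoot wild type 1 (0.972) and shoot AGR3/8 1 (0.974). It also met the share of probe sets under 16 on root AGR3/8 4 (48.6%) and the mean intensity of root AGR1/8 1 (147), root AGR3/8 1 (148) and shoot AGR1/8 2 (175). Over 24 groups of levels it met wild type replicate 4 on the reporter probe set, at 0.5 in root and 99.6 in shoot. Of 108 named root probe sets 7 had such an array in wild type, 18 in AGR1/7, 4 in AGR1/8 and 2 in AGR3/8, and 17 of the AGR1/7 arrays were replicate 1. Of 69 named shoot probe sets 12 had it in wild type, 3 in AGR1/7, 5 in AGR1/8 and 4 in AGR3/8, and 7 of the wild type arrays were replicate 1.

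Regrouping the arrays asked whether interchangeable arrays could give such counts. Only 1 grouping, the real arrangement, reached them for every count of probe sets. In the other groupings real differences between groups add to the spread within groups and lower the counts. The outcome therefore shows only that the arrays were not interchangeable. It cannot say whether the shared wild type arrays, or a single one of them, gave the counts. Interchangeable arrays were excluded for the transgenic mean (2027 in root against 382 at most elsewhere, 599 against 530 in shoot). They were also excluded for the calls in all 3 lines (119 against 10, 70 against 7) and the differences among lines (1139 against 1, 860 against 40). Each of these counts had 100 groupings. With 35 groupings per line the same held for AGR1/7 (940 against 1 in root, 609 against 3 in shoot), AGR1/8 (944 against 10, 693 against 28) and AGR3/8 (2064 against 1, 331 against 1). The same held for root against shoot in wild type (22566 against 6841 in 35 groupings) and for the difference of the effects (745 against 5 in 100). Chance was not excluded for the number of planned lists called, where 8 of 100 groupings in root reached the 6 lists called (highest other 9) and 11 of 100 in shoot reached 4 (highest other 7).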

How the results depend on the processing

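The joint removal of 2 arrays, the random block of line and number, the single-array ranges of the agreement between lines and the lists by symbol were chosen after the data were seen. No named value that passed in either fit reversed under any setting. In each tissue directions turned only in lists that were called there neither in the full fit nor under that setting, such as stress regulators (without 9 single arrays), phosphate regulators (6), aquaporins (5) and nitrogen transport (3) in root and cell cycle (4) in shoot, and splits of calls turned as given below and, for single arrays, in the report. The cause of the changes in count was not tested unless given. The full fits called 2027 (transgenic mean), 940, 944 and 2064 (AGR1/7, AGR1/8 and AGR3/8) root probe sets, 119 in all 3 lines and 1139 among lines, and in shoot 599, 609, 693, 331, 70 and 860. Values near background limit the rest, since 47.7% to 52.3% of the probe sets of each array lay under an intensity of 16.

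Without the filter on dim probe sets the root transgenic mean gave 1268, AGR1/7 560 and AGR3/8 1279, and in shoot the transgenic mean gave 385, AGR1/8 448, AGR3/8 156, all 3 lines 38 and the F test 429. With a larger dim share left out, so with fewer tests, root AGR1/7 gave 1519 and all 3 lines 195, shoot AGR3/8 582, root against shoot in wild type 14617 and the difference of effects 1160, and 2 planned shoot lists were called. Without the intensity trend root AGR1/7 gave 625, and shoot gave 318, 344, 369 and 140 for the transgenic mean and the lines, 30 for all 3 lines and 322 for the F test. Array weights gave 3261 in root AGR3/8, 179 in all 3 lines and 3670 in the F test, and in shoot 997, 1099, 1062 and 591, with 107 in all 3 lines and 2 lists. A minimum change of 1 log2 left 197 (77 higher, 120 lower), 180, 376 (157 and 219) and 372 (120 and 252) in root, 17 in all 3 lines and 493 in the F test. In shoot it left 65, 92, 186, 76, 23 and 222, between tissues 11026, and 178 (80 above, 98 below) for the difference of effects. The near-even split of root AGR1/8 (475 and 469) also turned without the filter (385 and 395), with a constant of 1 (428 and 467), without the trend (439 and 460), with array weights (567 and 666), with the replicate block (443 and 459), without root wild type 1 and AGR1/7 1 together (682 and 743) and without any single root array but wild type 2, wild type 4 and AGR1/7 1. A single fit of all 32 arrays gave 3881, 2569, 1549 and 4061 in root, 348 in all 3 lines and 1916 in the F test, and in shoot 681 for AGR3/8 and 2 lists. With the line as a random unit the transgenic mean gave 137 in root (6133 at an unadjusted p under 0.05) and 115 in shoot (3153). Without root wild type 1 and AGR1/7 1 together, AGR1/7 gave 608, AGR1/8 1425, all 3 lines 196 and the F test 2906, and without both wild type replicates 1 the difference of effects gave 281. An added constant of 1 gave 452 for the difference of effects and a constant of 64 gave 1226. With the wild type arrays split, the mean correlation of line effects was 0.261 in root and 0.192 in shoot. Lists that lost their call were root P450 (0.273) and shoot diterpenoid (0.201) with the larger dim share out, shoot phosphate regulators (0.0939) without the filter, shoot diterpenoid (0.0550 and also in the single fit) and phenylpropanoid (0.178) with array weights, and root cell cycle (0.104) and auxin (0.267) without root wild type 1 and AGR1/7 1, besides those in the report. Too few members of root pathogenesis-related, shoot nitrogen transport and shoot water deficit genes were left to test with the larger dim share out, and of the last in the single fit. Lists called only under a setting were root calcium and shoot cytokinin (0.0344), potassium (0.0293) and sugar (0.0404) without the filter, root calcium with a constant of 64, root diterpenoid (0.00463) with array weights, shoot cell wall (0.0415) with the replicate block, and root diterpenoid (2.58e-05) and transcription factors without root wild type 1 and AGR1/7 1, besides those in the report. None of them held with an estimated correlation. With an estimated correlation camera called 0 planned root lists (2 at an unadjusted p under 0.05) and 1 shoot list.

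Quantile normalization took shoot AGR3/8 to 202. Median centring moved the split of calls by more than 10 points for root AGR3/8 (865 higher and 942 lower, against 1222 and 842), shoot AGR1/7 (208 and 388, against 333 and 276), shoot AGR3/8 (99 and 155, against 174 and 157) and all 3 lines in shoot (32 and 15, against 55 and 15), and took the shoot transgenic mean to 256 and 263. The largest shift of a median change was −0.0548 log2. Of 126 named root values all but 3 kept their call under quantile normalization and all but 4 under median centring, and of 85 in shoot 83 and 82. The root calls lost were Lsi1 (adjusted p = 0.273), JAZ4 (0.0689) and a Cht2 probe set (0.0564) under quantile normalization and JAZ4 (0.0598), CXXS1 (0.0608), Rictpi2 (0.0539) and IAA23 under median centring. In shoot CAD (0.0629) and LOC4336765 were lost under quantile normalization, and GSA (0.0801) and a chaperonin probe set (0.0807) under median centring. The other settings kept 93 root and 65 shoot values (no filter), 108 and 61 (no trend), 103 and 85 (array weights), 114 of 125 and 82 (constant 1), 124 and 79 (constant 64), 118 and 76 (all arrays), and all 110 and 67 that could be tested with the larger dim share out.

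Leaving out each array in turn, the root transgenic mean ranged from 783 (without wild type 1) to 3023 (wild type 2), AGR1/7 from 386 (its replicate 3) to 1095 (wild type 2) and AGR3/8 from 428 (its replicate 3) to 3546 (wild type 2). Calls in all 3 root lines ranged from 62 (AGR1/8 2) to 255 (wild type 2) and the F test from 736 (AGR1/8 1) to 2134 (wild type 1). The shoot transgenic mean ranged from 224 (wild type 3) to 1026 (AGR3/8 1), AGR1/7 from 311 (wild type 3) to 713 (AGR3/8 1), AGR1/8 from 230 (its replicate 2) to 983 (its replicate 1) and AGR3/8 from 107 (its replicate 3) to 1413 (its replicate 1). Calls in all 3 shoot lines ranged from 27 (wild type 3) to 121 (AGR3/8 1), the F test from 257 (AGR3/8 2) to 1773 (AGR3/8 1) and planned shoot lists from 2 (wild type 1) to 5. The difference of effects ranged from 313 (shoot wild type 3) to 1606 (root wild type 2). Of 120 called root values 63 held without any single array, of 80 in shoot 50, and of 57 differences of effect 33.

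Over all groups the replicate numbers did not meet the level set for pairing, and the labels do not say that equal numbers are the same plant. Same-numbered root arrays correlated above 0.1 in 9 of 24 pairs (from −0.17 to 0.42) and shoot arrays in 1 of 24, and 6 of 16 root and 8 of 16 shoot arrays correlated best with their own number. The highest mean correlations of equal numbers were 0.197 for root wild type with AGR1/8 (above 0.1 for numbers 1 to 3, −0.154 for number 4) and 0.145 for root AGR1/8 with AGR3/8 (above 0.1 for all 4). Root and shoot arrays of equal line and number correlated between −0.0338 and 0.246, and the fit of all arrays treats them as unpaired. With line and number as a random block (correlation 0.0423) the difference of effects gave 1026 and root against shoot in wild type 22839. With the replicate block root AGR1/7 gave 586, shoot AGR3/8 882 and all 3 lines in shoot 132, the root auxin list was not called (0.0759), and 111 named root and 84 named shoot values kept their call.

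The planned values of alanine aminotransferase and of the promoter's gene were not run, because no gene name in the table matched either.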

Other observations

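The genes in this part were chosen after their values were seen, and no explanation was tested for them. Several named root genes had changes that the text has not yet given. MYBS1, a MYB factor of the sugar response, rose by 0.78 ± 0.16 log2 (adjusted p = 0.0131, 12 of 12 arrays above the wild type mean), and lost its call without root wild type 1 (0.0516). SWEET4, a sugar transporter, fell by 0.58 ± 0.13 (adjusted p = 0.0183, 0 of 12 above) and lost its call without the same array (0.0667). SAT2 on the amino acid list rose by 0.43 ± 0.09 (adjusted p = 0.0146, 12 of 12), lost without root wild type 3 (0.0508). DAHPS1, a partner of DAHPS2 at the start of the shikimate pathway, fell by 0.78 ± 0.17 (adjusted p = 0.0211, 0 of 12 above), lost without root wild type 3 (0.0688).

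The laccases LAC15 and LAC3 of the phenylpropanoid list moved apart in root. LAC15 rose by 0.83 ± 0.17 log2 (adjusted p = 0.0141, 12 of 12 arrays above) and LAC3 fell by 0.80 ± 0.18 (adjusted p = 0.0186, 0 of 12 above), and without root wild type 1 neither was called (0.0564 and 0.0731). Both kept their direction under quantile normalization and median centring. The dehydrin Dhn1 fell by 0.64 ± 0.14 in root (adjusted p = 0.0172, 0 of 12 above), and lost its call without root wild type 1 (0.0637). In shoot the kinase CIPK3 fell by 0.72 ± 0.14 (adjusted p = 0.00907, 1 of 12 above), lost without shoot wild type 3 (0.0527).

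On LOC4331398 the AGR3/8 arrays fell apart by replicate. In root their intensities were 128.9, 1495, 1595 and 86.0 in replicates 1 to 4, and in shoot 75.8, 310, 263 and 46.3, so replicates 1 and 4 were the lower in both tissues. The other lines had no root array under 1834 and no shoot array under 600. Wild type arrays were at most 13.2 in root and 11.4 in shoot.

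The mean intensity ran from 147 to 152 in root and from 158 to 213 in shoot, where AGR3/8 2 was highest and wild type 1 lowest. The same 2 arrays held the highest and lowest mean of the photosynthesis genes by symbol, at 10.9 and 10.2 log2. The ratio of the actin control probe sets at the 3′ and 5′ ends ran from 4.41 to 6.13 in root and from 5.32 to 12.4 in shoot, with the highest on AGR3/8 3. For GAPDH it was the reverse, with 2.43 to 57.0 in root and 1.52 to 27.2 in shoot.

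Pairs of lines shared more calls than independent calls would give, in a design where lines share their wild type arrays. In root AGR1/7 and AGR3/8 had 309 higher probe sets in common (18.5 for independent calls), against 129 for AGR1/7 and AGR1/8 (7.20) and 189 for AGR1/8 and AGR3/8 (15.2). In shoot AGR1/7 and AGR1/8 had 184 (3.69), against 61 for AGR1/7 and AGR3/8 (1.52) and 78 for AGR1/8 and AGR3/8 (1.93).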
